A study of Mus musculus with 6 samples.

How the data were processed

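Hearts of male mice were perfused on a Langendorff apparatus, and 3 Sham hearts were compared with 3 hearts arrested by cardioplegia for 30 min and reperfused for 1 h, per the labels' protocols. Poly(A) RNA was isolated and libraries were made with a NEBNext Ultra II kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19.1.403, fastp 0.23.0, HISAT2 2.1.0 and HTSeq 0.10.0, and the builds GRCm39, GRCm38 and mm10, without saying which step each served. The annotation, the strand setting and whether reads were counted per gene or per transcript are not given in the sources used here. The deposited values are FPKM per transcript, computed by the authors, for each of the 6 libraries. The related microRNA measurements named in the study's design were not analysed here.

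The table had 21198 rows, of which 40 repeated another and were dropped, leaving 11745 rows of protein-coding transcripts (8969 genes, 6952 of them with 1 row) and 9413 of lncRNAs. FPKM of transcripts of a gene were summed. Coordinates are those of the table. Of 8599 genes compared with the spans of a GRCm38 RefSeq annotation, 95.3% overlapped by at least 50%, and they are given as GRCm38. No coordinates were given for 798 lncRNAs.

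The number of reads behind each value was recovered because FPKM of 1 library are whole multiples of 1 read divided by length and total. Rows of mRNA and lncRNA had different totals, 7233171 to 9902397 and 2025331 to 2792592 reads, found up to a whole factor that was set by the lengths of genes with 1 exon. Whole reads (within 0.001, lengths from 30 bases) were found for 11744 of 11745 mRNA rows and 9413 of 9413 lncRNA rows. On simulated data with known totals, 98.7% of 2997 rows gave every read count exactly. The 10 most abundant genes held 14.7% to 17.3% of the reads of listed protein-coding transcripts and 49.5% to 51.7% of lncRNA reads.

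Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 5041 protein-coding genes and 7073 lncRNAs, and 6268 were left out. The values log2(FPKM + 1) were fitted with limma 3.58.1 in R 4.3.3 (group as the only factor, moderated variances with a trend, two-sided, Benjamini-Hochberg adjustment over all 12114 genes, adjusted p under 0.05). Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 25 lists with at least 5 genes tested, and with camera with an estimated correlation and fry beside it. Members of each list were also adjusted over the list alone, without a correction across the lists. Transcript rows were tested in the same way. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

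The 33 gene lists, the test, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 protein-coding genes and 5 lncRNAs per direction that passed, or else those with the smallest unadjusted p, up to 4 members of each list, and 12 genes in any case. Genes named outside it are said to have been chosen after their values were seen, and for the lists further members are given as examples. An item that the rule named is not reported here. The alternatives were other pseudocounts, filters, scalings, variance models, weights and thresholds, a replicate block, the most abundant transcript per gene, and each library left out. Alternatives chosen after seeing the data were limma voom on the recovered reads, camera with a variance trend and camera among protein-coding genes.

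The procedure was tested on simulated data, 5 runs of 12114 genes. The simulated spread between hearts varied by gene and was scaled to the median of the real genes with more reads. The procedure called 102 of 500 genes changed 2-fold, 334 of 500 changed 4-fold and 42 of 59421 unchanged genes. A list changed 1.5-fold was called in 5 of 5 runs and 0 of 125 tests of other lists were called. Simulated genes were drawn independently, without correlation between genes of a heart. The 0 of 125 therefore does not measure how often lists are falsely called in the real data. An exploratory camera test over the table's pathway annotation was also run after the data were seen. It is not reported, because its calls differed with the set of genes the pathways were compared against.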

Results

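RNA was measured in 6 hearts of male mice that had been perfused outside the body on a Langendorff apparatus, which keeps an isolated heart beating by perfusing its coronary vessels. In 3 Sham hearts contraction was not interrupted. In 3 I/R hearts (ischaemia and reperfusion) a cardioplegic solution, which arrests the heart, stopped contraction for 30 min, and 1 h of reperfusion followed. Abundance was given as FPKM, fragments scaled by transcript length and library total, for 8969 protein-coding genes and 9413 long non-coding RNAs (lncRNAs). The totals behind the FPKM of protein-coding genes were 9902397, 9643195 and 7233171 reads in Sham replicates 1, 2 and 3 and 7690040, 8896834 and 7827563 in I/R replicates 1, 2 and 3. For lncRNAs they were 2792592, 2709391 and 2025331 in Sham and 2213168, 2597795 and 2350913 in I/R. The protein-coding transcripts listed held 36.8% to 39.9% of their total and the lncRNAs 99.8% to 99.9% of theirs. Fos, Hspa1a and Myh7 had no transcript in the table. For protein-coding genes with a transcript, the part of a gene's reads that the listed transcripts held is not known. This limits every list of protein-coding genes below.

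The comparison of I/R with Sham hearts asks which mRNAs and lncRNAs differ 1 h after a cardioplegic arrest. Inflammatory genes and immediate-early genes, which respond to stress within minutes without new protein, were higher in I/R hearts as groups. Their median log2 changes were 1.11 and 0.61 over 13 genes tested each, of 26 and 30 genes in these lists. Genes of the extracellular matrix, of the stress response of the endoplasmic reticulum and of macrophages were higher by medians of 0.41, 0.19 and 0.22, and markers of ventricular cardiomyocytes were lower by a median of −0.27. These 6 of 25 lists had an adjusted p under 0.05 in limma's camera with a preset correlation between genes of 0.01, and 0 of 25 had one with an estimated correlation, where the smallest adjusted p was 0.348. All changes are I/R minus Sham in log2(FPKM + 1), a scale that understates the change of genes near or below 1 FPKM. Group values are means ± SD and changes are given ± SE, with n = 3 hearts per group.

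**Figure D1:**
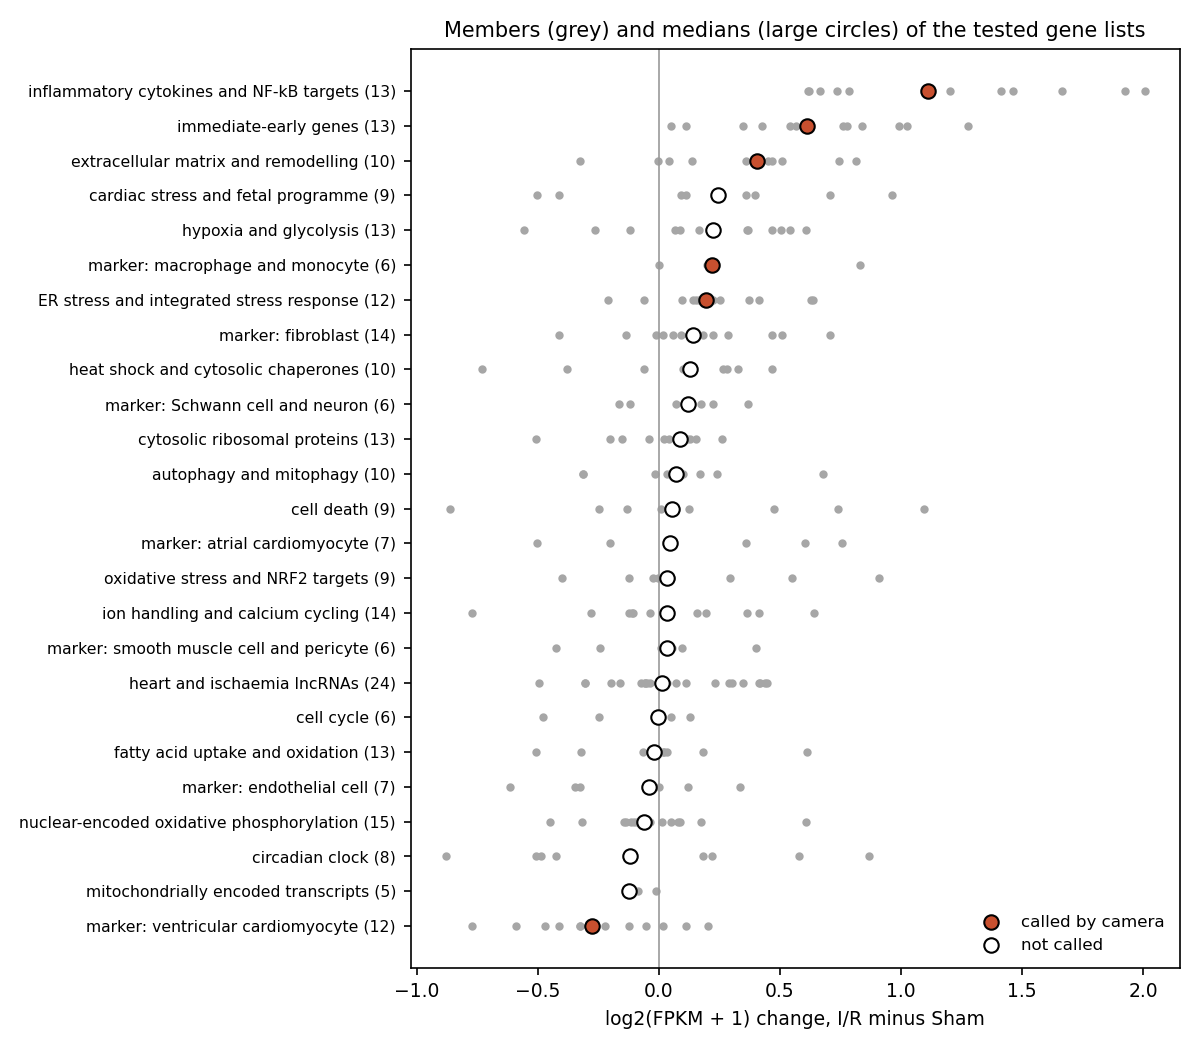
Change in log2(FPKM + 1), I/R minus Sham with 3 hearts per group, of each gene (grey points) and the median (large circles, filled where camera with the preset correlation called the list) of the 25 gene lists, with the number of genes tested in parentheses. The inflammatory list lies highest at 1.11 and the list of ventricular cardiomyocyte markers lowest at −0.27.

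No single gene had an adjusted p under 0.05: limma called 0 of 5041 protein-coding genes and 0 of 7073 lncRNAs, with a smallest adjusted p of 0.385. At an unadjusted p under 0.05 there were 173 protein-coding genes higher and 84 lower in I/R, and 340 lncRNAs higher and 426 lower, 1023 in all where 606 were expected by chance. On the reads recovered from the FPKM, limma voom called 0 genes after adjustment and 1026 at an unadjusted p under 0.05, of which 735 were shared. By class these were 228 protein-coding genes higher and 177 lower and 272 lncRNAs higher and 349 lower. With each class fitted alone the counts were 296 and 159 protein-coding genes and 267 and 305 lncRNAs, so the split by class and direction depended on the fit. The 3 I/R hearts lay all above or all below the 3 Sham hearts for 1656 genes, 13.7% of those tested, where chance gives 10%. The smallest adjusted p within the lncRNAs alone was 0.254 and within the protein-coding genes alone 0.696.

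Of the 10 protein-coding genes higher in I/R with the smallest unadjusted p values, none passed the adjustment over all genes (limma, adjusted p from 0.385 to 0.386). Ifnb1 (ENSMUSG00000048806), which encodes interferon beta, had 3 reads over the Sham hearts and 48 over the I/R hearts, and reached 2.6 ± 0.75 FPKM in I/R. Klf6 (ENSMUSG00000000078, GRCm38 chromosome 13, 5861482 to 5870394), a zinc finger transcription factor, was at 111 ± 9.23 FPKM in Sham and 165 ± 3.59 in I/R (0.56 ± 0.09). Bcl2l11 (ENSMUSG00000027381, chromosome 2, 128126038 to 128162547), which encodes the pro-apoptotic protein BIM, was at 6.35 ± 0.37 and 14.9 ± 3.65 FPKM (1.09 ± 0.20). Nfkbie, an inhibitor of NF-kB, was at 0.807 ± 0.353 FPKM in Sham and 3.8 ± 1.23 in I/R. Rgs16, a regulator of G protein signalling, differed by 1.34 ± 0.26, Sdcbp by 1.06 ± 0.21, the kinase gene Pim1 by 0.98 ± 0.20 and Fam43a by 0.56 ± 0.11. Rps12-ps3 (0.66 ± 0.11) is a pseudogene that shares sequence with Rps12, so its reads are uncertain.

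Among protein-coding genes lower in I/R, Pln (ENSMUSG00000038583, chromosome 10, 53337667 to 53345987) encodes phospholamban, the inhibitor of the calcium pump of the sarcoplasmic reticulum. It was at 116 ± 15.8 FPKM in Sham and 68.2 ± 14.0 in I/R (−0.77 ± 0.17; limma, adjusted p = 0.386 over all genes), and it was past 0.05 when adjusted over the list alone for ventricular markers (0.0357) and for ion handling (0.0416). The lncRNA Gm47644, chosen after its values were seen, is annotated on the opposite strand inside Pln and was at 28159.6 ± 1599 FPKM in Sham and 26487 ± 1948 in I/R (−0.09 ± 0.09). FPKM of protein-coding genes and lncRNAs were scaled by different totals and are not on the same scale. In reads over the Sham hearts, Pln had 2868 and Gm47644 379660. Reads of overlapping genes cannot be told apart without strand, and the strand setting of the counting is not given in the sources used here. Ndufb5, a subunit of respiratory complex I, differed by −0.55 ± 0.13 and Pitpnm2 by −0.68 ± 0.17. Over settings that kept all hearts, Ndufb5 ranged from −0.58 to −0.20. The remaining genes had few reads: Gm11037 had 133 in Sham and 58 in I/R, Otub1 64 and 23, the DNA repair gene Ercc1 123 and 35, and the mitochondrial peptidase gene Pmpcb 48 and 11. Ppp1r14a had 119 and 49 reads, Mtg1 19 and 6, and Gm17482 7 and 1.

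The inflammatory list gave the largest difference of any list: all 13 genes tested were higher in I/R, with 8 at an unadjusted p under 0.05. The chemokine gene Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683) was at 21.6 ± 9.37 FPKM in Sham and 88.3 ± 30.9 in I/R (2.01 ± 0.37). Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047), a feedback inhibitor of cytokine signalling, was at 86.6 ± 26.9 and 282 ± 104 FPKM (1.66 ± 0.34). Sele (ENSMUSG00000026582, chromosome 1, 164048234 to 164057677), the endothelial adhesion molecule E-selectin, was at 6.33 ± 4.72 and 25.6 ± 13.5 FPKM (1.93 ± 0.51). These 3 genes passed 0.05 when adjusted over the list alone (limma, adjusted p = 0.012, 0.012 and 0.0305) and 0 genes passed over all genes. Ccl3, which lies beside Ccl4 and encodes a related chemokine, differed by 1.20 ± 0.41, Il6 by 1.46 ± 0.60 (1.77 ± 1.34 and 7.2 ± 4.57 FPKM), Il1a by 1.41 ± 0.55, Ccl7 by 1.10 ± 0.46 and Ptgs2, the inducible cyclooxygenase, by 1.11 ± 0.57, none past 0.05 over the list alone. The camera test gave an adjusted p of 4.24e-09 with the preset correlation and an adjusted p = 0.351 with an estimated correlation, and fry gave an adjusted p of 0.148. The call with the preset correlation held without each of the 6 hearts in turn, with medians from 0.83 to 1.62. Some regroupings of the 6 hearts that mixed Sham and I/R also had this list called.

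**Figure D2:**
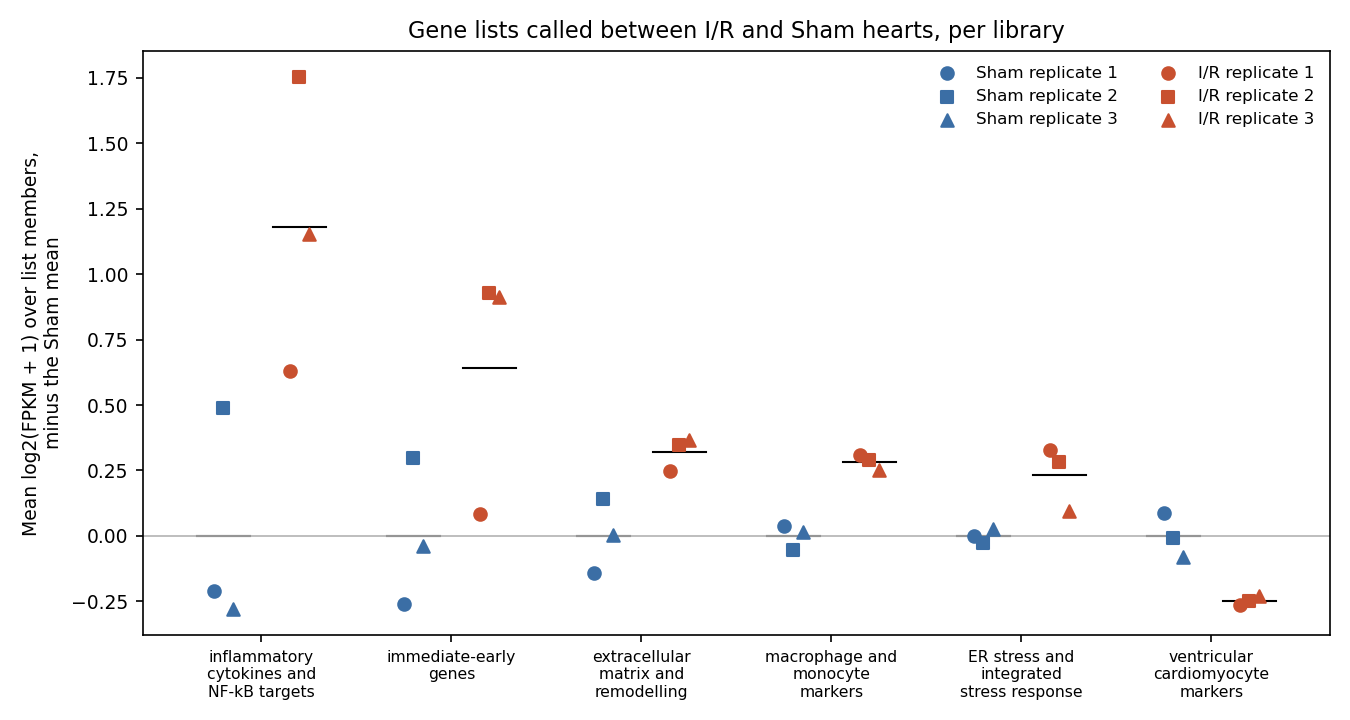
Mean over the genes of each called list of log2(FPKM + 1), relative to the mean of the 3 Sham hearts, for each heart of the Sham and I/R groups (points) with group means (bars). The inflammatory list reached 0.63, 1.75 and 1.15 in I/R replicates 1, 2 and 3 and lay between −0.28 and 0.49 in Sham.

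All 13 immediate-early genes tested were higher in I/R, with 5 past 0.05 when adjusted over the list alone and 0 over all genes. Klf6 had the smallest of these p values (limma, adjusted p = 0.00786), followed by Myc (0.0165), which was at 3.57 ± 0.603 FPKM in Sham and 10.4 ± 3.45 in I/R (1.28 ± 0.28). Klf4 (0.61 ± 0.17), the growth arrest gene Gadd45b (1.03 ± 0.28) and Zfp36 (0.99 ± 0.28), whose protein promotes decay of cytokine mRNAs, each had an adjusted p of 0.0264. Jun, at 520.0 ± 126 and 919 ± 353 FPKM, differed by 0.76 ± 0.34 and Egr1 by 0.35 ± 0.21, both above 0.05 over the list alone. The camera test gave an adjusted p of 1.5e-06 with the preset correlation and an adjusted p = 0.56 with an estimated correlation, and fry gave an adjusted p of 0.304. By the mean of the list, I/R replicate 1 (0.09) lay within the Sham hearts (−0.26 to 0.30), while I/R replicates 2 and 3 were at 0.93 and 0.91. The call with the preset correlation held without each heart in turn, with an adjusted p of at most 0.00305, and the median of 0.61 was 0.98 without I/R replicate 1. Some regroupings of the hearts that mixed Sham and I/R also had this list called. Atf3 was below the filter, at no more than 0.134 FPKM in any heart.

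Of 10 extracellular matrix genes, 8 were higher in I/R (camera adjusted p = 0.0136 with the preset correlation, adjusted p = 0.348 with an estimated correlation, fry adjusted p = 0.148). Col1a1 (ENSMUSG00000001506), a chain of collagen I, was at 92.1 ± 17.1 FPKM in Sham and 130.1 ± 6.71 in I/R (0.51 ± 0.14), the secreted protease gene Adamts1 differed by 0.75 ± 0.29, Mmp3 by 0.82 ± 0.32, Col5a2 by 0.36 ± 0.15 and Col3a1 by 0.47 ± 0.19. None of them passed 0.05 over the list alone (limma, adjusted p = 0.093 for each of these 5). With 1 heart left out, Mmp3 ranged from 0.48 to 1.10 and Col3a1 from 0.26 to 0.64. The call was lost without Sham replicate 1 (adjusted p = 0.0714) and without I/R replicate 3 (0.0593), and the median of 0.41 was 0.19 with no filter.

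Of 12 genes of endoplasmic reticulum stress, 10 were higher in I/R (camera adjusted p = 0.0228 with the preset correlation, adjusted p = 0.348 with an estimated correlation, fry adjusted p = 0.148). The chaperone gene Hsp90b1 differed by 0.41 ± 0.17, from 3.51 ± 0.296 to 5.0 ± 0.119 FPKM, the eIF2alpha phosphatase subunit gene Ppp1r15a by 0.63 ± 0.30, the asparagine synthetase gene Asns by 0.64 ± 0.30 and the transcription factor gene Xbp1 by 0.25 ± 0.15, with 0 past 0.05 over the list alone. The call was lost without Sham replicate 1 (adjusted p = 0.0714), Sham replicate 2 (0.0601), I/R replicate 1 (0.062) and I/R replicate 2 (0.0598). The median of 0.19 was 0.31 without Sham replicate 1 and 0.39 without I/R replicate 3.

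The 12 ventricular cardiomyocyte markers tested were lower in 9 cases and higher in 3 (camera adjusted p = 0.0228 with the preset correlation, adjusted p = 0.348 with an estimated correlation, fry adjusted p = 0.0418). After Pln, cardiac troponin T (Tnnt2, ENSMUSG00000026414) differed by −0.47 ± 0.13, from 40.0 ± 2.14 to 28.7 ± 3.89 FPKM. Myh6, the alpha heavy chain of cardiac myosin, differed by −0.33 ± 0.16 and the ventricular light chain Myl2 by −0.33 ± 0.15. In Sham hearts together, Tnnt2 had 1158 reads and Myh6 279, and the part of these genes' reads that the listed transcripts held is not known. Myl2 ranged from −0.46 to −0.20 with 1 heart left out, and Myh6 from −0.39 to −0.18 over settings that kept all hearts. The most abundant markers differed less, with Fabp3 at 0.02 ± 0.07 and Hspb7 at −0.12 ± 0.09, and the titin gene Ttn differed by −0.05 ± 0.11. The call was lost without Sham replicate 1 (adjusted p = 0.114), Sham replicate 2 (0.0601) and I/R replicate 1 (0.062), and the median was −0.17 without I/R replicate 1.

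All 6 macrophage markers tested were higher in I/R (camera adjusted p = 0.0228 with the preset correlation, adjusted p = 0.348 with an estimated correlation, fry adjusted p = 0.0418). Cd14, a receptor for bacterial lipopolysaccharide, was at 28.1 ± 2.38 FPKM in Sham and 52.3 ± 15.3 in I/R (0.83 ± 0.23), whereas the abundant Lyz2 differed by 0.22 ± 0.10 and the complement genes C1qa and C1qb by 0.22 ± 0.11 and 0.20 ± 0.10. The call was lost without Sham replicate 1 (adjusted p = 0.0622), Sham replicate 2 (0.126), I/R replicate 1 (0.0618) and I/R replicate 3 (0.0593). Camera did not call fibroblast markers (14 genes, median 0.14, adjusted p = 0.096), endothelial markers (7 genes, −0.04, 0.519), atrial cardiomyocyte markers (7 genes, 0.05, 0.557), smooth muscle and pericyte markers (6 genes, 0.03 with a mean of −0.02 and a median of −0.00691 after quantile normalization, 0.904) or Schwann cell and neuron markers (6 genes, 0.12, 0.519). The atrial median ranged from 0.0321 without I/R replicate 2 to 0.78 without I/R replicate 1, and the Schwann cell and neuron median was 0.0162 without Sham replicate 3 and 0.0344 without I/R replicate 1. Fibroblast markers were called without Sham replicate 2 (0.0415) and without I/R replicate 2 (0.0376). Too few markers were tested of neutrophils (1), lymphocytes (0), blood (3), adipocytes (2), epicardium (3), skeletal muscle (3) and lung (1). In these lists Il1r2 had 3 reads in Sham and 9 in I/R, Aldh1a2 differed by 0.66 ± 0.26, Fasn by 0.44 ± 0.27 and Hbb-bs by −0.54 ± 0.49. With 1 heart left out, Aldh1a2 ranged from 0.42 to 0.85, Fasn from 0.29 to 0.72 and Hbb-bs from −1.05 to −0.11. Acta1 differed by 0.96 ± 0.79, Hopx by −0.03 ± 0.22 and Ckm by 0.11 ± 0.18.

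Camera called none of the metabolic lists. Genes of hypoxia and glycolysis had a median of 0.22 over 13 genes (adjusted p = 0.0551), with Adm, the vasodilator adrenomedullin, at 0.54 ± 0.15 and Eno1 at −0.56 ± 0.21, and the list was called without Sham replicate 3 (adjusted p = 0.0158). Its median was 0.15 without Sham replicate 1, 0.13 with no filter and 0.37 with a filter at 5 FPKM. Genes of fatty acid oxidation had a median of −0.02 (13 genes, adjusted p = 0.935), with Acsl1 at 0.61 ± 0.22. Nuclear genes of oxidative phosphorylation had a median of −0.06 (15 genes, 0.808) and mitochondrially encoded transcripts one of −0.12 (5 genes, 0.703), with mt-Nd1 at 11019 ± 188 FPKM in Sham and 10438 ± 3120 in I/R. Genes of ribosomal proteins had a median of 0.09 (13 genes, 0.808). Some members of the lists of nuclear genes had low values, such as Cox4i1 at 0.928, Rps9 at 0.544, Gapdh at 0.512 and Cd36 at 0.669 FPKM in Sham. Mitochondrially encoded transcripts were also uneven, with mt-Co2 at 7.48 and mt-Nd3 at 21.2 FPKM in Sham beside mt-Nd1 at 11019. The part of a gene's reads that the listed transcripts held is not known. Genes of oxidative stress had a median of 0.04 (9 genes, 0.519), with the metallothionein genes Mt2 and Mt1 at 0.91 ± 0.29 and 0.55 ± 0.19 and Hmox1 at 0.30 ± 0.71.

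Stress and death genes outside the called lists included single genes past 0.05 over their list alone. With many lists and no correction across them, some such genes arise by chance. Bcl2l11 was past it among 9 cell death genes (limma, adjusted p = 0.00815; list median 0.06, camera adjusted p = 0.462), where the anti-apoptotic Bcl2l1 differed by −0.86 ± 0.31. Map1lc3b, which encodes the autophagosome protein LC3B, was past it among 10 autophagy genes (0.037; 0.68 ± 0.16; list median 0.07, or 0.00137 without Sham replicate 1, camera adjusted p = 0.519). The transcription factor gene Irf1 was past it among the 4 interferon response genes tested (0.0371; 1.47 ± 0.41), a list too short for camera. Cytosolic chaperones had a median of 0.13 (10 genes, adjusted p = 0.519), which ranged from 0.0583 to 0.26 with 1 heart left out, with Hspb8 at 0.33 ± 0.11 and Dnajb4 at −0.73 ± 0.21, and Hspa1b was below the filter. The cardiac stress list had a median of 0.25 (9 genes, 0.468), which was 0.11 without Sham replicate 1 and 0.12 without I/R replicate 3, with Ankrd1 at 716 ± 152 FPKM in Sham and 1162 ± 196 in I/R (0.71 ± 0.19) and the natriuretic peptide gene Nppa at 0.36 ± 0.30, and Nppb was below the filter. Nppa ranged from 0.11 without Sham replicate 1 to 0.62 without Sham replicate 2, and Acta1 from 0.38 to 1.80 without the same hearts. Genes of ion handling had a median of 0.04 (14 genes, 0.904). Clock genes had a median of −0.12 (8 genes, 0.935), although camera ranked them higher in I/R, with Bhlhe40 at 0.87 ± 0.23. Cell cycle genes had a mean of −0.09 (6 genes, 0.545).

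**Figure D3:**
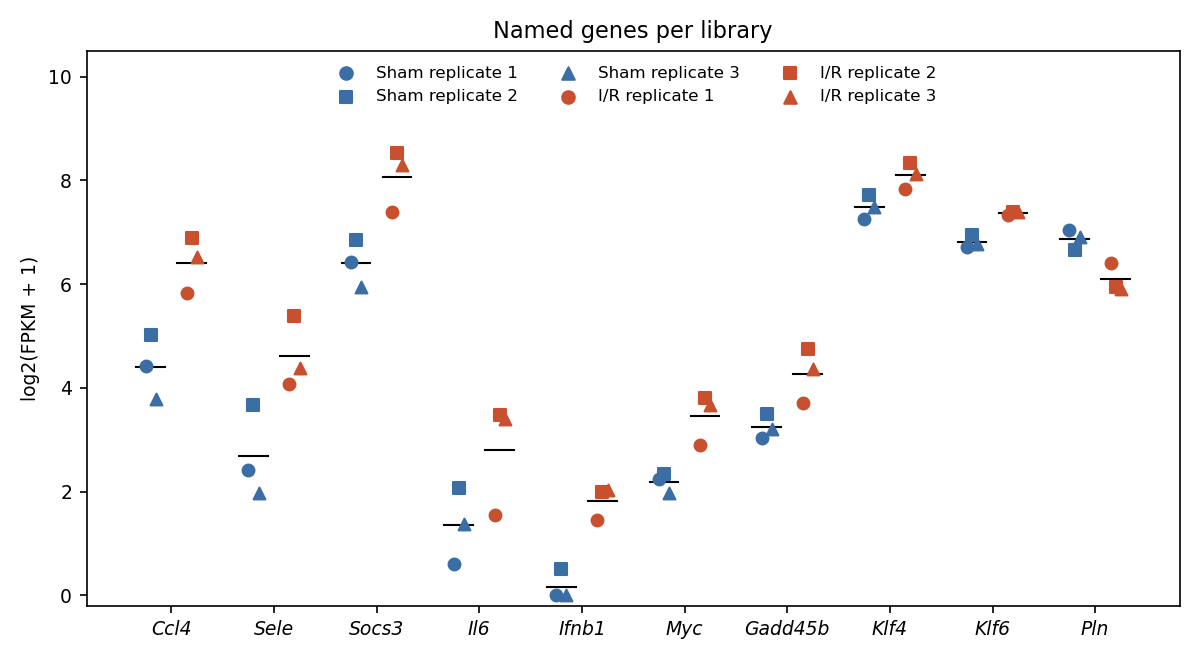
Abundance as log2(FPKM + 1) of selected genes in each of the 3 Sham and 3 I/R hearts (points, with a shape per replicate) and the mean of each group (bars). Ccl4 was at 21.6 FPKM on average in Sham and 88.3 in I/R, and Pln at 116 and 68.2.

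Among lncRNAs, Mir133a-1hg (ENSMUSG00000095438), the host transcript of a microRNA of heart and skeletal muscle, was at 502 ± 44.0 FPKM in Sham and 315 ± 21.2 in I/R (−0.67 ± 0.10). Gm20100 (ENSMUSG00000110245, chromosome 8, 11457471 to 11459742) was at 10.6 ± 0.803 and 36.5 ± 10.8 FPKM (1.66 ± 0.22), Gm43150 differed by 0.94 ± 0.14 and 6720427I07Rik by −0.59 ± 0.09. Other lncRNAs with small p values rested on few reads: Gm29336 had 1 read in Sham and 19 in I/R, 4930522N08Rik 7 and 32, Gm50354 0 and 3, Gm48556 18 and 1, Gm39158 8 and 0, and Gm46559 8 and 0. None passed the adjustment (limma, adjusted p = 0.385 for each of these 10). Of 24 lncRNAs known from heart or ischaemia, 13 were higher and 11 lower, with a median of 0.01, or −0.0219 after quantile normalization (camera adjusted p = 0.519) and 0 past 0.05 over the list alone. Rian differed by 0.41 ± 0.15, Dnm3os by 0.42 ± 0.15, Mhrt, which is antisense to Myh7, by −0.30 ± 0.12, and Neat1 by 0.07 ± 0.19. Malat1 was at 32810.0 ± 1617 FPKM in Sham and 32779 ± 3048 in I/R.

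With 3 hearts per group, the test recovered 20.4% of genes simulated with a change of 2-fold and 66.8% of those with 4-fold. In that simulation, smaller changes of single genes were mostly not detectable. Simulated genes were independent, with a spread scaled to genes with more reads, so the shares may differ in the real hearts. Across genes, which are not independent replicates, Sham replicate 2 correlated most with I/R replicate 3 (r = 0.971) and I/R replicate 1 with Sham replicate 1 (0.966). The median SE of a change was 0.21 for protein-coding genes and 0.25 for lncRNAs.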

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

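The settings limma voom, camera with a variance trend and camera among protein-coding genes were chosen after the results were seen. Under each alternative limma called 0 protein-coding genes and 0 lncRNAs at an adjusted p under 0.05, with a smallest adjusted p from 0.0881 (without I/R replicate 2) to 0.485 and from 640 (filter at 5 FPKM) to 1222 (no filter) genes at an unadjusted p under 0.05. The threshold of an unadjusted p under 0.05 with an absolute log2 change of at least 1 gave 24 protein-coding genes higher and 11 lower and 72 lncRNAs higher and 83 lower in I/R. Of 25 lists 6 were called, 0 with an estimated correlation, 2 with fry (ventricular and macrophage markers) and from 2 to 7 when 1 heart was left out, with 2 without Sham replicate 1, 3 without I/R replicate 1 and 7 without Sham replicate 3. Each of the 6 kept its direction, and the inflammatory and immediate-early lists kept their calls in every camera setting with the preset correlation, with medians from 0.83 to 1.67 and from 0.52 to 0.98. Beyond the hearts left out, macrophage markers lost their call with no filter (adjusted p = 0.061), quantile normalization (0.058) and voom (0.0535), and the endoplasmic reticulum list with a filter at 5 FPKM (0.233). Hypoxia genes gained a call with that filter (0.047), array weights (0.0375) and a variance trend (0.0418), and fibroblast markers with filters at 1 (0.0484) and 5 FPKM (0.019) and a variance trend (0.0445). The cause was not tested.

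Results that changed sign had no call in either direction, and the cause was not tested. In median log2 change, oxidative stress genes were at −0.017 with voom, ion handling genes at −0.001005 with no filter and −0.00697 with voom, and clock genes at 0.18 and 0.20 with filters at 1 and 5 FPKM. Cell cycle genes were at 0.0176 with quantile normalization and 0.0081 with the most abundant transcript, heart lncRNAs at −0.0219 and smooth muscle markers at −0.00691 with quantile normalization. Cnn1 was at 0.0299 with the most abundant transcript and 0.0785 with voom, and Hopx at 0.0109 with array weights. With 1 heart left out, medians ranged from −0.13 to 0.10 for oxidative stress, −0.0542 to 0.0651 for fatty acid oxidation, −0.19 to 0.0144 for oxidative phosphorylation and −0.33 to 0.15 for mitochondrially encoded transcripts. They ranged from −0.047 to 0.0965 for ribosomal proteins, −0.0338 to 0.21 for cell death, −0.0567 to 0.15 for ion handling, −0.24 to 0.0241 for clock genes and −0.19 to 0.13 for the cell cycle. For heart lncRNAs the range was −0.0115 to 0.0681, for endothelial markers −0.27 to 0.00331 and for smooth muscle markers −0.0319 to 0.12. Single genes ranged from −0.51 to 0.16 (Usp18), −0.33 to 0.12 (mt-Nd1), −0.23 to 0.14 (mt-Nd5), −0.63 to 0.00446 (Cnn1), −0.64 to 0.10 (Hbb-bt), −0.16 to 0.0254 (Cidea), −0.0018 to 0.21 (Ckm), −0.22 to 0.0732 (Hopx) and −0.41 to 0.85 (Hmox1).

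With the replicate number as a block, 0 genes passed an adjusted p under 0.05 (smallest 0.115), 1125 had an unadjusted p under 0.05 and 6 lists were called, and no call changed. Libraries with the same number had correlations of their deviations from the group means of 0.15, 0.03 and 0.03, so the numbers were not taken as pairs, and Sham replicate 2 correlated more with I/R replicate 3 (0.11) than with I/R replicate 2. Among 12963 transcript rows limma called 0, with 1109 at an unadjusted p under 0.05, and 3 of 764 genes with several rows had rows at that level in opposite directions. The camera tests used variances without a trend, except in the setting named for a variance trend. Lists were not tested with robust variances, and of the classes fitted alone only with protein-coding genes. Depth limits single genes with few reads: 3928 protein-coding genes and 2340 lncRNAs lay below the filter.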

Other observations

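The tests on exchanged libraries, on cell shares, on minor transcripts and on other splits of the hearts were chosen after the results were seen; those on depth and on overlapping genes were written before their result, the latter after some lncRNAs at heart genes had been looked at. The lncRNAs given here that overlap genes of heart muscle, chosen after their values were seen, differed by less than 0.5 in log2. At Myh6, Gm49130 differed by −0.30 ± 0.12, at Myh7 Gm31251 differed by −0.39 ± 0.08 and Gm29015 by −0.20 ± 0.18, at Ckm A930016O22Rik differed by 0.29 ± 0.10 and at Ttn Gm13938 differed by 0.03 ± 0.08. At Atp2a2, the gene of the calcium pump that Pln inhibits, Gm43359 differed by −0.42 ± 0.11, Gm43360 by −0.49 ± 0.10 and Gm43361 by −0.11 ± 0.07. At Ryr2, the gene of the calcium release channel, Gm47493 differed by −0.07 ± 0.13 and Gm47494 by −0.29 ± 0.41. None passed limma's adjustment over all genes.

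Inflammatory and immediate-early genes were higher in I/R, and I/R replicate 1 lay nearest to Sham (0.63 and 0.09 by list mean) and Sham replicate 2 nearest to I/R (0.49 and 0.30). More macrophages as the whole cause is argued against by the median of their markers, 0.22 with an upper quartile of 0.22, against 1.11 for the inflammatory list. An exchange of Sham replicate 2 and I/R replicate 1 cannot be told apart from the labels: the exchanged split separated 1 of the 25 lists where the labels separated 7 and other splits 0 to 4, but it also had the inflammatory and immediate-early lists called and had 1048 genes at an unadjusted p under 0.05 against 1023. Thinning to the same depth left 1.01 of the inflammatory difference (0.978 to 1.04 over 100 draws). Over 5040 protein-coding genes, thinning shifted the log2 change by a median of 0.0038 in absolute value, with a 90th percentile of 0.0528. FPKM are already scaled by the library total, and thinning moved most genes little. The test could therefore hardly have come out otherwise and cannot decide whether depth was a cause of the inflammatory difference. The immediate-early list was not thinned. Neutrophils, of which 1 marker was tested, handling during perfusion, and arrest and reperfusion themselves stay open and were not tested.

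Ventricular cardiomyocyte markers were lower in I/R, by −0.77 ± 0.17 for Pln and −0.47 ± 0.13 for Tnnt2, while Fabp3 was at 0.02 ± 0.07. A lower share of cardiomyocytes as the whole cause would lower all 12 markers alike, and their heterogeneity p was 0.000324 (Q = 34.3 on 11 degrees of freedom). That p took errors of genes as independent and the SE, estimated from few hearts, as known, so it may be too small. Listed transcripts that hold a small part of a gene's reads may also change unlike the gene. The test therefore cannot decide whether a lower share of cardiomyocytes was the whole cause, which stays open. The abundant lncRNAs at the loci of Pln, Myh6, Ckm and Ttn had a median of −0.029 where these 4 genes had −0.19. With 4 loci, a change of the genes themselves cannot be told apart from one of minor transcripts that hold a small part of the genes' reads. An effect of arrest and reperfusion on single mRNAs stays open and was not tested.

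Changes of lncRNAs followed those of protein-coding genes they overlap: across pairs of genes, which are not independent replicates, Pearson's r was 0.312 over 1639 overlapping pairs and 0.0818 over 2906 neighbours within 50 kb. The difference was 0.23 (95% bootstrap interval 0.158 to 0.297, 2000 draws), where reads shared between overlapping genes would give a higher r for overlapping pairs. The draws took pairs as independent and did not include the spread between hearts. The r was 0.338 for the 1045 pairs on opposite strands and 0.277 for the 594 on the same strand, so a part of the differences of antisense lncRNAs may be that of the overlapping gene. Transcription of both genes of a pair from a shared open locus stays open and was not tested.

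The 6 hearts form 10 splits, too few for a share under 0.05. All 10 splits gave 0 protein-coding genes, 0 lncRNAs and 0 transcript rows past the adjustment, the labels included. At an unadjusted p under 0.05 the labels gave 1023 genes and the highest other split 1048, so 2 splits gave as many. For lncRNAs the labels gave 766 and the highest other 810, again 2 splits, and for protein-coding genes 257 and 238, with 1 split as high. The labels gave 6 called lists and the highest other split 3, with 1 split as high. The inflammatory and immediate-early lists were also called in other splits. Both were called with Sham replicates 1 and 2 grouped with I/R replicate 1, and with Sham replicates 1 and 3 grouped with it. Both were also called with Sham replicate 1 grouped with I/R replicates 2 and 3. With Sham replicates 1 and 3 and I/R replicate 3 as a group, the inflammatory list was called. Calls of these lists were thus not particular to the labels. The split with 1048 genes was that with Sham replicate 2 and I/R replicate 1 exchanged. Atrial cardiomyocyte markers varied between hearts of a group, at −1.05, 0.50 and 0.54 in Sham replicates 1, 2 and 3 and −0.85, 1.37 and −0.05 in I/R. Mitochondrially encoded transcripts were at 0.32, −0.65 and 0.03 in I/R replicates 1, 2 and 3.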
